A study of Mus musculus with 2 samples.

How the data were processed

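H3K27ac ChIP-seq peak lists of 2 libraries of mouse MA9 leukaemia cells were analysed, 1 from Gata2 f/f and 1 from Gata2 KO cells. Per the labels, leukaemia cells from bone marrow of primary animals were transduced with Cre or a control vector, sorted for the fluorescent markers and used for ChIP after 7 to 9 days in culture. The groups follow the genotype in the labels. Reads were aligned to mm10 and peaks were called in broad mode with BWA, SAMtools and MACS2, per the submitters' processing notes and the format of the lists. Versions, options, duplicate handling, the control library and read numbers are not given in the sources used here, so that depth is unknown. Each list comes from 1 library, and no replicate was pooled or compared.

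Each peak carries a position, a score, a fold enrichment over the background (a ratio), a -log10 p-value and a -log10 q-value, all deposited by the authors. The score of the deposited lists was not used. The fold and -log10 values were used to rank or filter peaks within a list, never to compare a peak's height between lists. The lowest -log10 q was 1.01 in both lists. A list made from more reads, or with a better enrichment, holds more and wider peaks, so that a difference in covered bases can come from the calls as well as from the chromatin. The f/f peaks were fewer with a higher median -log10 p. Peak widths had a median of 1207 bp in f/f and 1166 bp in KO.

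Peaks on chromosomes 1 to 19, X and Y were kept. Overlap needed at least 1 bp, and bedtools 2.31.1 gave the same counts. Shares have 95% Wilson intervals, which cover counting error only. Genes came from a table of assembly GRCm38.p6, the same build as mm10, with 21883 protein-coding genes on these chromosomes. The table gives gene starts and ends but no strand or transcripts. For that reason the planned promoter window at transcription start sites was replaced by both gene ends: a gene counted as marked when a peak lay within 1000 bp of either end, and as marked in 1 library alone when the other list had no peak within 5000 bp of either end. Peaks at 3' ends and at a neighbour's promoter are therefore counted too. Distal peaks lay over 2000 bp from any end and were alone when the other list had no peak within 1000 bp. Strong peaks had a -log10 p at or above their list's median. Domains were peaks stitched within 12000 bp, leaving out only peaks wholly within 2000 bp of a gene end. They were ranked by covered bases, the first 500 per list being compared. Distances of peaks and domains to genes are to the nearer gene end, in kb. A planned search for GATA motifs in distal regions needs the genome sequence and is not reported.

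Locus coverage was the percent of bases of a gene and 25 kb on both sides under peaks. For each of 23 gene lists, fixed before the data were examined, the median KO minus f/f difference was placed among 10000 random lists of protein-coding genes of the same size, matched in 20 bins of mean coverage. A list outside the central 95% (below percentile 2.5 or above 97.5) was called apart from random lists, as a description of these libraries and not as a test of genotype. The lists held Hoxa and MLL-fusion targets, GATA2 partner factors, stem cell, mast cell and basophil, erythroid, megakaryocyte, neutrophil, monocyte, dendritic, B, T and NK, and stromal and endothelial genes. They further held drug efflux, apoptosis, p53, cytarabine and anthracycline metabolism, DNA repair, cytokine signalling, inflammation, interferon, cell cycle, ubiquitously expressed and other-organ genes. Of 504 symbols 500 were found, and 20 stood in more than 1 list. Many markers of other blood lineages are also expressed in progenitors and leukaemia cells, so that a list's name does not identify a cell type.

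The genes named in the text followed a rule fixed before the data were examined. It took Gata2, then per direction the 8 genes marked by a strong peak in 1 library alone with the highest fold, and the 6 genes with the largest difference in locus coverage, 1 per overlapping locus. Per list it took up to 4 members marked in 1 library alone or, where there were none, the 2 members with the largest difference each way. It also took 3 domains and 5 distal regions per direction, with predicted and receptor-family genes skipped among the first kinds. All members of the Hoxa and GATA2 partner lists could be named. Some genes that the rule takes are not reported here. Other genes were chosen after their values were seen: the sex-linked genes, genes at blank chromosome starts or interior stretches, S100a8, Ltf, Ly6g, Elane, Prtn3, Ctsg, Mpo, Ms4a3, Mmp8, Mmp9, Ngp, Itgb7, Il4, Mcpt8, Abca2, Abca7, Abcb1a, Abcb1b and Abcc5.

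Alternatives fixed in advance were peaks with a -log10 q of at least 5, the same number of peaks from each list (34272), the strongest 20000, at least 3-fold enrichment, other overlap rules, gene-end windows of 500 and 2000 bp, flanks of 10, 50 and 100 kb, and other numbers, stitching and ranking of domains. Added after the data were seen were results without the 6 chromosome starts at which 1 list had no peak and the other at least 10, results for chromosomes 1 to 19 only, random lists matched on the strongest peak in the locus or in 100 bins, 1 gene per overlapping locus, for the Hoxa list strongest-peak matching with 1 gene per overlapping locus, and the GATA2 partner list without Gata2. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for plots. The steps were tested on simulated data. From the f/f list (34272 peaks), 200 of 200 removed distal regions and 200 of 200 genes given a peak were recovered, with 0 other regions and 8 neighbouring genes called. The simulated KO list was made from the f/f list itself, so that these counts check the steps and not noise between libraries. Of 200 random lists of 25 genes, 6.5% fell outside the central 95%, and 100% of lists shifted up by 2 points were recovered. Recovery of smaller or downward shifts was not tested, while the 6 gene lists below the central 95% had medians of -0.52 to -1.57 points.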

Results

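Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by ChIP-seq in mouse leukaemia cells driven by the MLL-AF9 fusion (MA9 cells). The cells came from bone marrow and carried either the floxed, intact Gata2 gene (Gata2 f/f, 1 library) or a deletion of it (Gata2 KO, 1 library). They were kept for 7 to 9 days in medium with IL-3, IL-6 and SCF before chromatin was collected. Gata2 encodes a GATA transcription factor of haematopoietic stem and progenitor cells, and the study asks about its part in drug resistance of acute myeloid leukaemia. With 1 library per genotype, no difference given here has a replicate check, and every comparison describes these 2 libraries. The f/f list held 34313 peaks and the KO list 37302, of which 34272 and 37234 lay on chromosomes 1 to 19, X and Y and were compared. Read depth behind the lists is unknown. The f/f peaks had a median -log10 p of 12.2 and a median fold enrichment of 3.51, and the KO peaks 9.41 and 3.09. These are the authors' own values for each peak and serve only to rank or filter peaks within a list.

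The libraries also differed in marks of sex and at the starts of some chromosomes. Xist, the RNA that silences 1 X chromosome in female cells, had a peak at a gene end in f/f (-log10 p 35.3) and none in KO. The Y-linked genes Uty, Kdm5d and Eif2s3y had such a peak in KO and none in f/f, and Ddx3y had none in either. The f/f list had no peak before position 4587644 on chromosome 6, 10494779 on chromosome 7, 5333703 on chromosome 18 and 4194303 on chromosome 19, where the KO list had 214 peaks. The KO list had none before 4459322 on chromosome 4 and 4278889 on chromosome 13, where the f/f list had 42. These 6 chromosome starts held 260 protein-coding genes, 105 of them with a gene-end peak in the other list, among them ribosomal and respiratory chain genes such as Rps9, Rpl28, Ndufs8 and Ndufv1. Counts of genes and of distal regions found in 1 list alone are given with and without these starts, as are gene lists with members there.

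**Figure D1:**
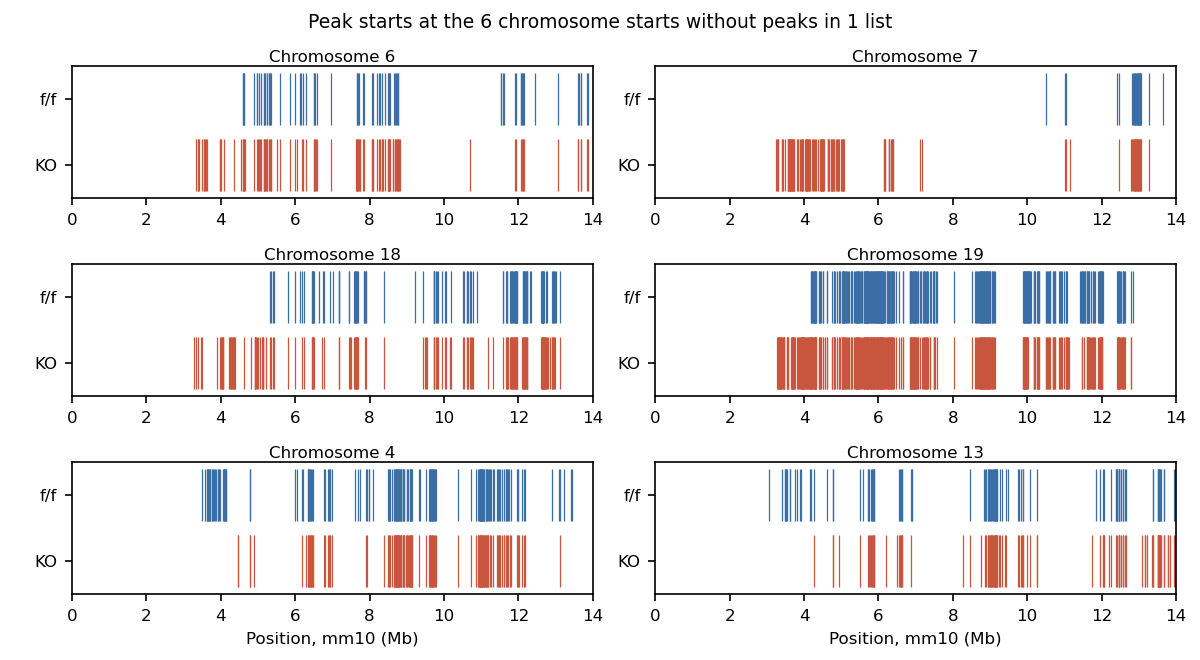
Starts of H3K27ac peaks in the Gata2 f/f list (blue, upper rows) and the Gata2 KO list (red, lower rows) along chromosomes 6, 7, 18, 19, 4 and 13, each vertical line marking 1 peak against position in Mb (mm10). On chromosomes 6, 7, 18 and 19 the f/f rows begin later than the KO rows, and on 4 and 13 the KO rows begin later.

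The Gata2 gene itself (chromosome 6, 88193891 to 88207032, mm10) was marked in both libraries, with less of its surroundings covered in KO. Peaks covered 15.4% of the gene and its 25 kb flanks in f/f, in 7 peaks, and 8.41% in KO, in 5 peaks, a difference of -6.99 percentage points. Among 1094 protein-coding genes of similar coverage, this difference lay at percentile 0.823. Inside the gene, f/f had peaks at 88196738 to 88198975 and at 88203382 to 88203849 that no KO peak overlapped. The latter starts 9.49 kb from the gene's lower coordinate, in the part of the gene that holds its known intronic enhancer. It was a weak call, with a -log10 p of 6.22, below the f/f median of 12.2, and weak f/f peaks were less often shared. The peak at 88196738 to 88198975 lay above that median (20.1). Upstream, on the side of the known distal Gata2 enhancer, both lists had a peak starting 78.1 kb (f/f) and 77.5 kb (KO) before the gene, 2778 and 1301 bp wide. Over 100 kb flanks the coverage was 11.7% in f/f and 7.10% in KO, a difference of -4.60 points, which is over 1.5 times smaller. The peaks at the gene ends were present in both lists but narrower in KO (946 against 1185 bp, and 831 against 1167 bp). Part of the coverage difference therefore lies in the width of shared calls. H3K27ac peaks do not check the deletion of coding sequence. Sequence removed in KO can give no peak, so that inside the gene missing DNA and missing acetylation cannot be told apart.

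**Figure D2:**
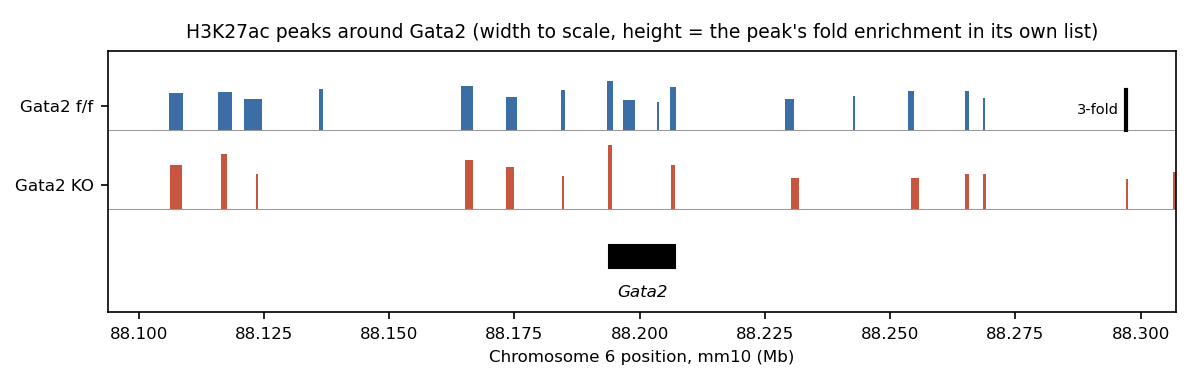
H3K27ac peaks of the Gata2 f/f list (blue) and the Gata2 KO list (red) around Gata2 on chromosome 6, against position in Mb (mm10). Each bar is 1 peak, its width to scale and its height the authors' fold enrichment within that list (scale bar, 3-fold). The f/f list has 7 peaks within 25 kb of the gene and the KO list 5.

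Most peaks were shared. Of the f/f peaks, 83.8% (95% Wilson interval 83.4 to 84.2, 28709 of 34272) overlapped a KO peak by at least 1 bp, and 77.4% of the KO peaks (77.0 to 77.9, 28837 of 37234) overlapped an f/f peak. Intervals cover counting error only. Sharing followed peak strength, from 50.3% in the weakest of 10 equal bins of f/f peaks by -log10 p to 99.5% in the strongest, and from 31.3% to 99.2% in KO. Peaks covered 46.3 Mb in f/f and 48.6 Mb in KO, a ratio of 1.05. That order turned with the threshold, the ratio being 0.951 among peaks with a -log10 q of at least 5 and 0.833 among peaks of at least 3-fold enrichment.

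At gene ends, 10424 of 21883 protein-coding genes had a peak within 1 kb of either end in both libraries. A gene-end peak in f/f with no KO peak within 5 kb of the ends was found for 401 genes, and the opposite for 351. Outside the blank chromosome starts these counts were 388 and 259. Among peaks at or above their list's median -log10 p, 117 genes were marked in f/f alone and 130 in KO alone, or 105 and 52 outside the blank starts. With peaks of at least 3-fold enrichment, the count in f/f alone was 844 and that in KO alone 273. When the other list could have a peak beyond 1 kb of the ends, they were 598 and 579.

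The f/f-alone genes with the highest fold in the f/f list were Pomc (8.81), the precursor of ACTH and other peptide hormones, Zfp507 (8.49), a zinc finger gene, Net1 (8.18), a RhoA exchange factor, and Rcn1 (8.02), an ER calcium-binding protein. The Pomc peak lay at the gene's upper coordinate (3959850 to 3960715), and with no strand in the gene table it cannot be taken as a promoter peak. Mdfic (7.98), Plekha5 (7.93), Garem1 (7.60) and Rundc3b (7.52) came next, and Fzd1 (7.43), a Wnt receptor, takes the place of Net1 when the blank starts are left out. Net1 lies in the blank start of chromosome 13. The KO-alone genes with the highest fold in the KO list were Rnf17 (8.51) and Tesmin (8.25), both germ-line genes, Acyp2 (7.68), an acylphosphatase, and Lipo3 (7.43). Cul2 (7.27), a ubiquitin ligase scaffold, Ndufa3 (7.26), a subunit of respiratory complex I, Zfp939 (7.21) and the X-linked Xlr (6.72) followed. Tesmin, Cul2 and Ndufa3 lie in blank starts of the f/f list, and outside these Lrig3 (5.94), the Y-linked Uty (5.89) and the calcium channel subunit gene Cacnb2 (5.42) join the list.

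Locus coverage, the percent of bases of a gene and its 25 kb flanks under peaks, was higher in KO by a wide margin around Tcirg1 (0 to 19.8%, f/f to KO), Cpt1a (0 to 17.5%) and Nudt8 (0 to 15.8%), all in the blank start of chromosome 19, and around Xbp1 and Gpr146. Xbp1, a transcription factor of the unfolded protein response, had 14.4% in f/f and 34.0% in KO, and Gpr146, an orphan receptor gene, 20.7% and 37.9%. Outside the blank starts, Klk1b9 (0 and 12.9%), the neutrophil calprotectin gene S100a9 (1.44% and 13.9%), Vmac (4.78% and 16.6%) and the recombination gene Rad51d (5.55% and 17.0%) followed. Coverage was lower in KO by the widest margin around C2cd4a (34.2% in f/f and 20.9% in KO), Bhlhe41, a circadian repressor (13.2% and 0.69%), and Exosc5, an RNA exosome subunit (35.5% and 24.3%). The cell cycle inhibitor gene Cdkn1b (23.9% and 13.3%), Hoxa7 (44.9% and 34.4%) and Irf8, a transcription factor of monocyte and dendritic cell development (17.5% and 7.30%), came next.

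Strong distal peaks, over 2 kb from any gene end, were found in 1 list alone more often in KO. Of 8124 such f/f peaks, 289 (3.56%, interval 3.18 to 3.98) had no KO peak within 1 kb, and of 9401 KO peaks, 606 (6.45%, 5.97 to 6.96) had no f/f peak. Outside the blank starts these were 276 and 565. Among peaks of at least 3-fold enrichment the order turned, with 1523 in f/f and 994 in KO. The f/f peaks of highest fold lay on chromosome 4 at 3874661 to 3875601, 2.56 kb from Mos and in a blank start, and on chromosome 1 at 170254919 to 170255941, 3.33 kb from Sh2d1b2. Others lay on chromosome X at 135885620 to 135886643 within Bhlhb9, on chromosome 1 at 136017727 to 136018722 within Igfn1, and on chromosome 13 at 9494469 to 9495441 within Dip2c. The KO peaks of highest fold lay on chromosome 10 at 24330724 to 24331292, 27.9 kb from Moxd1, and at 5718175 to 5718725, 70.6 kb from Vip. They were followed by peaks on chromosome 1 at 164224004 to 164224774, 3.73 kb from the coagulation factor gene F5, on chromosome 11 at 34864942 to 34866060, 31.3 kb from Spdl1, and on chromosome 15 at 85645707 to 85646665, 63.9 kb from Wnt7b.

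Distal peaks stitched within 12 kb formed 16721 domains in f/f and 17469 in KO. Of the 500 f/f domains with the most covered bases, 294 (58.8%, interval 54.4 to 63.0) overlapped 1 of the 500 KO domains ranked highest in the same way. The domain at Zfp217, a transcriptional repressor gene, led the f/f list with 29.6 kb covered, against 27.1 kb under KO peaks. Domains 77.4 kb from Tomm20 (27.1 kb, KO 28.2 kb) and at Ift57 (26.9 kb, KO 24.7 kb) followed. The KO domain with the most covered bases lay 57.3 kb from Tomm20 (32.1 kb, f/f 30.2 kb), followed by those at the cell cycle kinase gene Cdk6 (29.9 kb, f/f 17.9 kb) and at Zfp217 (29.1 kb, f/f 27.7 kb). The greatest excess in f/f was at Erg, an ETS factor of stem cells (chromosome 16, 95384920 to 95465633), with 26.8 kb covered in f/f and 12.4 kb in KO. A domain 20.6 kb from Pls3 had 10.0 and 0.953 kb and one 220.4 kb from Stk26 had 13.3 and 4.59 kb, both on the X chromosome, where Xist differed between the libraries. The greatest excess in KO was 49.6 kb from Ppara (chromosome 15, 85634195 to 85685305), with 20.8 kb in KO and 3.79 kb in f/f. This domain holds the KO-alone distal peak given above by its distance to Wnt7b, so that both describe the same locus. Domains at Susd1 and Ptbp3 (21.7 and 8.97 kb) and at Gpr146 (25.3 and 12.6 kb) followed.

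Locus coverage was then compared over 23 gene lists, 500 of whose 504 symbols were found. Each list's median difference (KO minus f/f, in points) is given with its percentile among 10000 random lists of the same size and similar coverage. Below the central 95% of random lists lay 6 lists and above it lay 1, against 1.15 expected outside by chance if genes and lists were independent. They are not, since neighbouring members share bases and 20 symbols stood in more than 1 list, so that more could fall outside by chance. Of the listed genes, 11 had a gene-end peak in f/f alone and 14 in KO alone, or 11 and 13 without the blank starts. The order turned with the same number of peaks from each list, to 17 and 12, and the counts were 26 and 31 when the other list could have a peak beyond 1 kb of the ends. Many gene-end peaks of list members in 1 list alone lay below their list's median -log10 p, where sharing was lower. The sex-linked marks and the separate blank starts go with genotype for every list below.

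**Figure D3:**
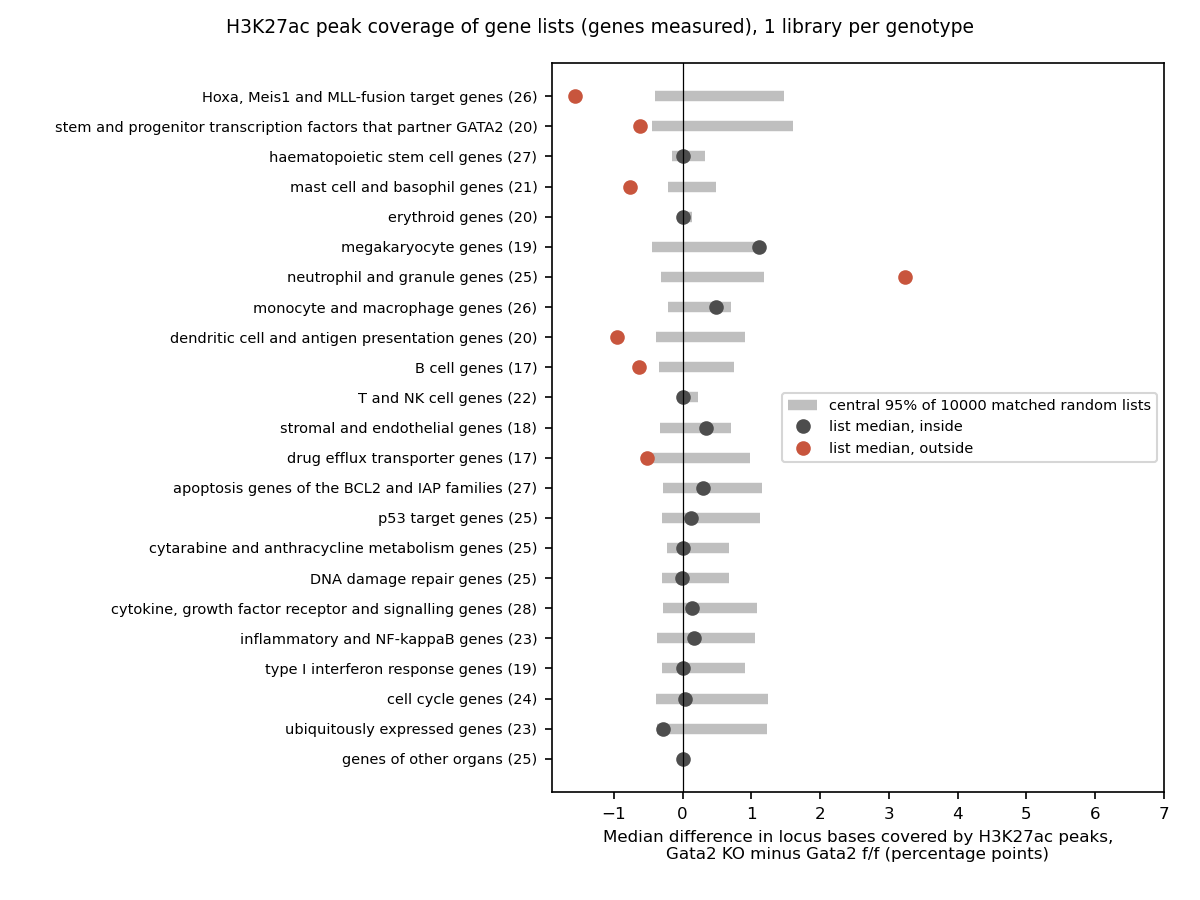
Median difference in the percent of locus bases covered by H3K27ac peaks, Gata2 KO minus Gata2 f/f in percentage points (horizontal axis), for each gene list (rows, number of genes in brackets). Grey bars span the central 95% of 10000 matched random lists, and red points are list medians outside that span. The Hoxa list lies at -1.57 and the neutrophil list at 3.24.

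Genes of the Hoxa cluster and other MLL-fusion targets, the core programme of MA9 leukaemia, had less H3K27ac coverage in KO. Of 26 members, 20 were lower in KO and 6 higher, with a median difference of -1.57 points (percentile 0.0). Hoxa9 was covered at 46.5% in f/f and 39.2% in KO, Hoxa10 at 42.3% and 35.6%, Hoxa3 at 25.9% and 16.0% and Hoxa11 at 40.8% and 32.6%. The receptor kinase gene Flt3 had 9.21% and 4.62%, the TALE homeobox gene Pbx3 5.82% and 1.71%, and its relative Meis1 12.5% and 10.5%. Mecom, which encodes the leukaemia oncoprotein EVI1, had a gene-end peak in f/f alone (-log10 p 6.98, below the f/f median of 12.2). Cdk6 (15.7% and 20.6%), Gfi1 (19.3% and 24.9%) and Myb (12.9% and 16.3%) were higher in KO. The medians of the members' coverage went the other way from the median difference, at 12.7% in f/f and 13.3% in KO. Neighbouring Hoxa genes share bases, and with 1 gene per overlapping locus the median difference was -0.52 points (percentile 2.04, 19 genes). With 10 kb flanks it was -0.92.

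The list of transcription factors known to work with GATA2, which includes Gata2 itself, was lower in KO in 13 of 20 cases and higher in 7, with a median difference of -0.62 points (percentile 1.14). Without Gata2, the deleted gene, 12 of 19 were lower and the median was -0.58 (percentile 2.06). After Gata2, the largest differences among members lower in KO were at Erg (11.6% in f/f and 6.03% in KO), Hhex (13.5% and 8.68%), Nfe2 (25.6% and 21.6%), the GATA cofactor gene Zfpm1 (9.09% and 5.53%) and Tal1 (5.70% and 2.26%). The myeloid factor gene Spi1 (13.6% and 17.7%), Lmo2 (16.1% and 19.2%) and Fli1 (11.5% and 14.1%) had higher coverage in KO. Runx1 (7.73% and 7.30%), Cebpa (16.1% and 16.7%) and Lyl1 (30.9% and 30.7%) differed by less than 1 point. The difference was larger, at -1.21 and -1.23, with 10 kb flanks and with the same number of peaks from each list. Ubiquitously expressed genes moved the same way under these settings, from -0.29 to -0.59 and -0.58, so that the growth is not particular to this list.

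Genes of haematopoietic stem cells went both ways, with 12 of 27 lower and 11 higher in KO and a median difference of 0.0 (percentile 44.1). Cd34, Angpt1, Rbpms and Mecom had a gene-end peak in f/f alone, and Hoxb4 and Gprc5c in KO alone. Of these, only the peaks at Angpt1 (-log10 p 21.8) and Hoxb4 (20.2) lay above their list's median. Coverage at Cd34 was 6.95% in f/f and 2.96% in KO, and at Hoxb4 0 and 5.29%.

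**Figure D4:**
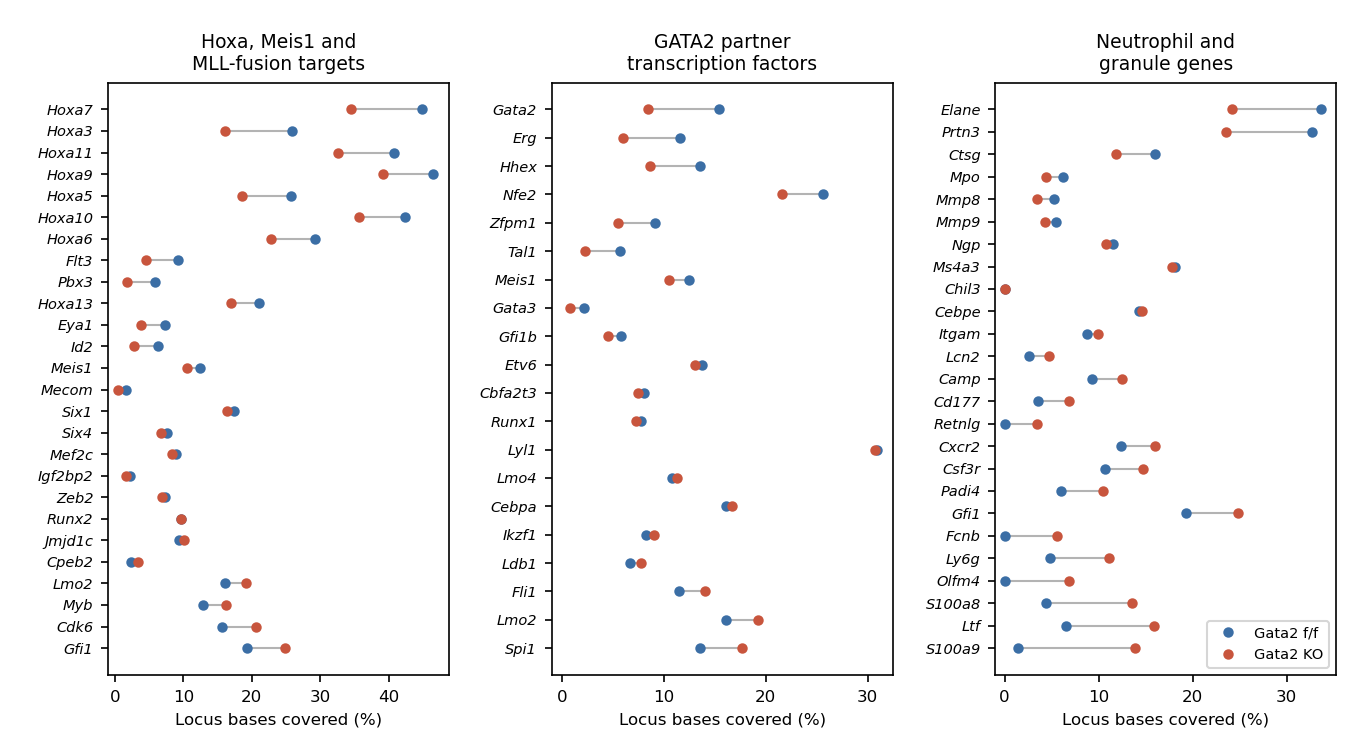
Percent of locus bases covered by H3K27ac peaks (horizontal axes) in Gata2 f/f (blue points) and Gata2 KO (red points) for each member of the Hoxa, GATA2 partner and neutrophil lists. Grey lines join the 2 libraries' values for a gene. Hoxa7 has 44.9% in f/f and 34.4% in KO, and S100a9 1.44% and 13.9%.

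Neutrophil and granule genes had more coverage in KO. Of 25 members, 16 were higher in KO and 8 lower, with a median difference of 3.24 points (percentile 100). S100a9, Fcnb (0 in f/f and 5.58% in KO), Olfm4 (0 and 6.85%) and Retnlg (0 and 3.42%), all genes of maturing neutrophils, had a gene-end peak in KO alone. These were weak calls, with a -log10 p of 3.02 to 7.71, below the KO median of 9.41. Chosen after their values were seen, S100a8 (4.35% and 13.5%), the lactoferrin gene Ltf (6.56% and 15.9%) and Ly6g (4.85% and 11.1%) were also higher. The azurophil granule protease genes Elane (33.6% and 24.2%), Prtn3 (32.7% and 23.6%) and Ctsg (16.0% and 11.8%) and the myeloperoxidase gene Mpo (6.16% and 4.42%) were lower in KO, as were the later granule genes Mmp8 (-1.72 points), Mmp9 (-1.17) and Ngp (-0.67). The size of this difference moved with the settings, and of those that follow only 50 kb flanks kept the list outside the random span. The median was 0.27 (percentile 65.3) with 10 kb flanks, 1.15 (99.1) with 50 kb flanks, 0.81 (97.4) with the same number of peaks from each list and 0.17 (92.5) among peaks with a -log10 q of at least 5.

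Monocyte and macrophage genes had a median difference of 0.49 points (percentile 93.5), 15 of 26 being higher in KO, and 0.0 (63.3) among peaks with a -log10 q of at least 5. The list lay just outside the random span, at percentile 97.54, with the same number of peaks from each list and with strongest-peak matching. Maf (-log10 p 5.15, below the KO median) and Mrc1 (13.7, above it) were among the members with a gene-end peak in KO alone. Irf8 was among the 6 genes with the largest difference toward f/f. Megakaryocyte genes had a median difference of 1.11 (percentile 97.3), with Gp1ba at 12.2% in f/f and 15.8% in KO and Nfe2 and Clec1b lower in KO. Gp6 (0 and 3.01%) lies in a blank start, and without these the median difference was 0.69. It was 0.22 (percentile 77.7) with 10 kb flanks, 0.44 (68.8) with 50 kb flanks, 0.27 (80.8) with the same number of peaks from each list and 0.0 (60.6) among peaks with a -log10 q of at least 5. Matching on the strongest peak took the megakaryocyte list outside the random span, at percentile 99.1. Erythroid genes differed by a median of 0.0 (percentile 47.3), with Tal1 and Tfrc lower in KO and Klf1 and Ermap higher.

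Mast cell and basophil genes had lower coverage in KO in 14 of 21 cases, with a median difference of -0.77 points (percentile 0.02). Chosen after their values were seen, Itgb7 (-4.37 points), Il4 (5.42% in f/f and 1.19% in KO) and the basophil protease gene Mcpt8 (15.8% and 11.7%) showed the largest differences. The locus of Mcpt8 overlaps that of Ctsg in the neutrophil list (16.0% and 11.8%), so that their differences are not separate observations. Il6 had a gene-end peak in f/f alone and Cd200r3 in KO alone, both below their list's median -log10 p (3.64 and 4.19). Among peaks with a -log10 q of at least 5 the median was 0.0 (percentile 59.0), and with 50 kb flanks it was -0.37.

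Dendritic cell and antigen presentation genes had a median difference of -0.96 points (percentile 0.04), 12 of 20 being lower in KO. Irf4 (5.42% in f/f and 1.91% in KO) and Clec9a (2.58% and 1.16%) had a gene-end peak in f/f alone. These peaks had a -log10 p of 4.7 and 10.5, below the f/f median of 12.2. The locus of Clec9a overlaps that of Clec1b in the megakaryocyte list. With 10 kb flanks the sign turned, to 0.15, and with 50 kb flanks the median was 0.12. B cell genes had a median of -0.63 (percentile 0.44), 10 of 17 being lower in KO, with the recombinase genes Rag1 (6.59% and 1.18%) and Rag2 (6.98% and 1.25%) lowest. Cd79a and Cd22 were higher in KO. The list fell back inside the random span in 4 of 8 alternatives. Its median was -0.01 (percentile 15.0) with 10 kb flanks, 0.0 (41.0) with 50 kb flanks, 0.0 (61.6) among peaks with a -log10 q of at least 5, and -0.01 (26.5) with 1 gene per overlapping locus, Rag1 and Rag2 sharing one. T and NK cell genes had a median of 0.0 (percentile 43.4), with a KO-alone peak at Tbx21. Their member Ncr1 lies in a blank start, and without it the median was 0.0 (percentile 45.9). Stromal and endothelial genes had a median of 0.34 (percentile 86.8), with a KO-alone peak at Cxcl12, and their member Col1a2 lies in a blank start, without which the median was 0.20 (percentile 75.3). With the same number of peaks from each list it was 0.0 (54.5), and with 10 kb flanks 0.56 (97.8), outside the random span.

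The list of drug efflux transporter genes, a group close to the study's question, also holds genes such as Abca1 and Abca7, which are chiefly lipid transporters. Its members were lower in KO in 12 of 17 cases and higher in 5. Their median difference was -0.52 points (percentile 1.82), although the medians of coverage were 5.31% in f/f and 5.43% in KO. Abca1 had a gene-end peak in f/f alone and Abcc3 in KO alone. Chosen after their values were seen, Abca2 had 13.3% in f/f and 9.65% in KO, Abca7 22.8% and 19.3%, and the multidrug resistance genes Abcb1b 2.11% and 0.75% and Abcb1a 0.67% and 0, while Abcc5 had 5.29% and 8.29%. Among peaks with a -log10 q of at least 5 the list lay at percentile 5.74 (median -0.42), and with 1 gene per overlapping locus at 2.72 (median -0.46).

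The other lists tied to drug response lay inside the random span. Cytarabine and anthracycline metabolism genes had a median difference of 0.0 (percentile 33.8), with a gene-end peak in f/f alone at the cytidine deaminase gene Cda and in KO alone at Gstp1, which lies in a blank start of the f/f list. Without Gstp1 the median was 0.0 (percentile 34.6). Apoptosis genes of the BCL2 and IAP families had a median of 0.3 (percentile 56.9), with Bcl2l2 (17.5% in f/f and 11.7% in KO) and Bid (12.8% and 8.35%) lower in KO and Bmf (10.4% and 16.8%) and Birc2 (3.46% and 6.97%) higher. For p53 targets the median was 0.12 (percentile 39.0), with an f/f-alone peak at Perp. For DNA damage repair it was -0.01 (percentile 34.6), with an f/f-alone peak at the Ku80 gene Xrcc5.

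Cytokine receptor and signalling genes had a median of 0.13 (percentile 40.0), with Flt3 and Il6ra lower in KO and the chemokine receptor gene Cxcr4 (14.6% and 19.1%) and Csf2rb higher. Inflammatory and NF-kappaB genes had a median of 0.17 (percentile 48.1) and type I interferon genes 0.0 (percentile 32.0), with Oas1a and Irf1 lower in KO and Isg15 and Bst2 higher. Cell cycle genes had a median of 0.03 (percentile 22.6), with Cdkn1b and Ccnd2 lower in KO and Cdkn2d (16.9% and 22.4%) and Cdkn1a (14.4% and 19.8%) higher. As a background, ubiquitously expressed genes had a median of -0.29 (percentile 4.23), with Actb (26.7% and 20.2%) and Gapdh (16.6% and 12.3%) lower in KO and Reep5 and Gpi1 higher. With 10 kb flanks they lay at -0.59 (percentile 1.33), outside the random span and on the same side as the Hoxa and GATA2 partner lists. The same number of peaks from each list gave -0.58 (2.81) and a -log10 q of at least 5 gave -0.54 (2.745), both inside. With 50 kb flanks the median was 0.02 (13.9). Genes of other organs had a median of 0.0 (percentile 49.2), with Gfap and Olig2 lower in KO and Nphs1 and Pou5f1 higher.

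Peak numbers per chromosome were close to the total ratio on the 19 autosomes, where the KO to f/f ratio ran from 1.02 to 1.18 with a median of 1.09. The highest was on chromosome 7, whose blank start in f/f held 98 KO peaks, and without the blank starts the range ended at 1.14, on chromosome 12. The X chromosome had fewer peaks in KO, 677 against 716, a ratio of 0.946. The Y chromosome had 4 peaks in KO and 0 in f/f.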

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

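No test is reported in this part, and the count was looked at after the lists had been compared. Peaks on unplaced and unlocalized scaffolds, which the comparisons left out, numbered 68 in KO and 41 in f/f. Of these, 18 KO and 2 f/f peaks lay on scaffolds assigned to chromosome 1, and 50 and 39 on the others. With no control library used here, they stand out only as signal outside the main measurement, and no explanation was tested.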

How the results depend on the processing

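The settings without blank chromosome starts, with chromosomes 1 to 19 only, with matching on strongest peaks or in 100 bins, with 1 gene per overlapping locus, alone or with strongest-peak matching, and without Gata2 were chosen after the data were seen. Over all results and settings, 210 values stayed on the same side or within their limits, 35 moved, 9 became weaker, 5 stronger and 3 were counted as turned. Those 3 were gene lists. Other orders that turned, such as the ratio of covered length, count as moved, and dendritic cell genes with 50 kb flanks (0.12) as weaker. Causes were not tested unless named. The outermost 5' end alone and the GATA motif comparison with its 3 alternatives were not run, for want of strand and sequence. No paired analysis was possible because there is 1 library per genotype. Read depth is unknown, so that the effect of depth on calls could be approached only by thresholds.

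With a -log10 q of at least 5, the shared percent was 81.25 in f/f and 85.32 in KO, the ratio of covered length 0.951, and distal regions alone 924 and 1315. With the same number of peaks from each list these were 81.24, 81.57 and 0.992, and with the strongest 20000 the KO percent was 84.36, the ratio 0.988 and the distal counts 1318 and 1992. With at least 3-fold enrichment the percents were 72.36 and 83.68, the ratio 0.833, f/f-alone genes 844 and distal regions 1523 and 994. With at least 50% of the peak covered the percents were 78.47 and 72.61. Without the blank starts the KO percent was 77.89 and the ratio 1.043. Distal regions alone numbered 4696 and 7314 with all peaks and 758 and 1383 when ranked by fold. Allowing another library's peak from 1000 bp on gave 598 f/f-alone and 579 KO-alone genes, and 26 f/f-alone and 31 KO-alone list genes; by construction a nearer limit lets more genes count. The same number of peaks gave 17 f/f-alone and 12 KO-alone list genes and an X ratio of 0.895. Domain sharing was 64.3% for 1000 domains and 49.0% with 5000 bp stitching. The Gata2 difference was -4.60 points with 100 kb flanks and -9.49 with the same number of peaks.

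The Hoxa and GATA2 partner lists stayed outside the random span in 9 of 9 alternatives, at percentiles up to 2.04 and 2.06. Mast cell genes did in 7 of 8, drug efflux and dendritic cell genes in 6, neutrophil genes in 5 and B cell genes in 4. Not every alternative could move a list. Other matching changes only the random lists, and 1 gene per overlapping locus left all 20 GATA2 partner genes in place. Among alternatives that changed flanks or peaks, only 50 kb flanks kept neutrophil genes outside. With 10 kb flanks, neutrophil genes weakened to a median of 0.27, B cell genes to -0.01, dendritic cell genes turned to 0.15, and stromal (0.56) and ubiquitous genes (-0.59) moved outside. With 50 kb flanks, dendritic cell genes stood at 0.12, their percentile being 32.6, and B cell genes at 0.0. With a -log10 q of at least 5, mast cell and B cell genes stood at 0.0 with percentiles of 59.0 and 61.6, counted as turned, neutrophil genes at 0.17 and drug efflux genes at -0.42. The same number of peaks weakened neutrophil genes to 0.81 and took monocyte genes (0.45) outside. Matching on the strongest peak took megakaryocyte (1.11) and monocyte genes (0.49) outside. With 1 gene per overlapping locus, B cell genes stood at -0.01 and drug efflux genes at -0.46. The remaining lists stayed inside.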

Other observations

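The tests of the sex-linked marks, of the blank chromosome starts, of neutrophil maturity and of a difference between animals were chosen after those results were seen; the matching on strongest peaks was set before its result was known, except in its form with 1 gene per overlapping locus. Several stretches inside chromosomes carried a run of peaks in 1 list alone. Around Ifng, the interferon gamma gene, a stretch of chromosome 10 (118325541 to 118779274) had 13 KO peaks and 0 f/f peaks overlapping them. Stretches with 10 KO peaks and none in f/f lay at B3galt1 and Stk39 on chromosome 2 and at Fstl4 on chromosome 11, and the longest, of 2941 kb, lay on chromosome X (53382679 to 56323202) around Xlr, where 3 of 10 were strong and the libraries also differ in sex marks. In the other direction, 12 f/f peaks at Zc3h12c on chromosome 9 (52102302 to 52289520), 11 at Fam155a on chromosome 8 and 10 each at Bbx on chromosome 16 and at Tcf4 on chromosome 18 (69574974 to 69805792) met no KO peak. Most of these peaks were weak, 2 of 13 at Ifng and 2 of 12 at Zc3h12c being at or above their list's median -log10 p.

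The Hoxa list had less coverage in KO and the neutrophil list more. Calls in the f/f list, whose -log10 p was higher, could be wider at strong loci. The Hoxa list would then move into the random span once random lists are matched on the strongest peak. The list stayed at percentile 0.0, and at 1.59 with 1 gene per overlapping locus. That matching replaced matching on coverage, so that wider f/f calls at highly covered loci, such as Hoxa, are not excluded. Ubiquitously expressed genes, also lower in KO by median, lay at percentile 2.92 under it, against 4.23. The neutrophil list's percentile of 100 decides nothing, since such calls would lower coverage in KO and not raise it. Whether a larger share of maturing neutrophils in the KO culture could account for the neutrophil list stays open: 5 progenitor-stage genes (Mpo, Elane, Prtn3, Ctsg, Ms4a3) had a median of -4.2 points and the other 20 a median of 3.51, but this split was made after the values were seen and decides nothing. Weak peaks called in KO leave peak calling open too, the median being 0.17 among peaks with a -log10 q of at least 5. A difference between the 2 animals or leukaemias rather than Gata2 cannot be told apart, since 3 of the Y-linked genes were marked in KO and 0 in f/f and each genotype has 1 library.

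Peaks were missing from the starts of 6 chromosomes in 1 list or the other. Loss in the making of the lists may account for this but was not decided: the smallest start held 15 peaks of the other list and no interior stretch more than 13, but the starts were picked for being blank. Peak numbers run through with 0 missing in both lists, so that peaks taken out of a numbered list are argued against and a loss before that stays open. Loss of both copies of the chromosome ends from the cells is argued against by 7 genes of the ribosome, complex I and the spliceosome in them that are marked in the other list (Ndufa3, Prpf31, Rps9, Rpl28, Ndufs8, Ndufv1 and Rps20), since cells depend on such genes. This holds only for the starts that contain such a gene. Of the 7, 6 lie in starts blank in f/f and 1, Rps20, in a start blank in KO. Just beyond the blank starts, 267 of 276 strong peaks (96.7%) were overlapped by the other list.

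Xist was marked in f/f and Y-linked genes in KO. Origin of the libraries in animals of different sex may account for both, the f/f peak at Xist having a -log10 p of 35.3. Loss of the Y chromosome from male f/f cells is argued against by that same peak, of 3.2-fold enrichment, since male cells do not silence an X chromosome. The 2 libraries would then come from separate leukaemias, so that genotype and animal go together in every comparison.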
